A study of Mus musculus with 12 samples.

How the data were processed

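Bulk RNA sequencing of liver was available for 12 male mice, 3 each in fed control, fasted control, fed knockout and fasted knockout groups. Per the labels' protocols, RNA was taken from frozen liver and strand-specific libraries were made from poly(A) RNA. Per the submitters' processing notes, the tools used were bcl2fastq 2.19, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.3 and DESeq2 1.24.0 with genome build mm10. The notes give no role or order for these tools, and the strand setting, the handling of reads that match several places and the annotation release are not given in the sources used here. The authors deposited raw counts per Ensembl gene, with 1 column per library, and a second table in TPM, a length-scaled unit, over the same genes. The deposited TPM values sum to 1000000 in each library and equal the deposited counts divided by 1 fixed length per gene, with a largest relative deviation of 4.4e-08 over 12379 genes with enough counts. Group labels were taken from the sample titles, and all 12 columns could be assigned to a sample. Gene positions are those of the annotation in the deposited tables.

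Totals ranged from 17520058 to 22414976 counts. Of 55487 genes, 26344 had 0 counts in all libraries. The filterByExpr rule of edgeR removed 39625 genes and left 15862, which held at least 99.87% of the counts of each library. At these totals, the median counting error of a tested gene in 1 library was 29% under 1 CPM, 14% from 1 to 5 CPM, 6.8% from 5 to 20 CPM and 3.1% above, beside an observed spread between replicates of 43%, 26%, 13% and 10%. The squared spread beyond counting exceeded the squared counting error for 58.8%, 72.3%, 80.9% and 95.8% of the genes in these ranges. Normalisation used trimmed mean of M values (TMM) factors, which ranged from 0.923 to 1.12.

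Genes were tested on the raw counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions. All 12 libraries entered 1 fit with a mean for each group, so the groups share an estimate of the spread, and the 6 comparisons were contrasts of these means. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, and the threshold was an adjusted p of 0.05 with no minimum fold. Levels are CPM scaled by the TMM factors. Replicate numbers were not used as a pairing, since the labels state none.

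For groups of genes, 40 lists were written from general knowledge, covering metabolic pathways, stress and inflammation, sex-biased liver genes, tissue handling and markers of liver and other cell types. They name 616 genes, of which 38 were not tested. Some genes are in more than 1 list, so results of such lists are not independent of each other. Lists were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01 between genes, which compares a list with all other tested genes, and adjusted over the 39 lists that held at least 3 tested genes. The list of exocrine pancreas markers had 0 tested genes and was left out. Counts of list members are given over all tested genes and adjusted over the list alone. With the correlation estimated for each list, 0 lists passed in any of the 6 comparisons, against 15, 8, 6, 9, 16 and 19 with the preset value in the order knockout against control fed, fasted and mean, fasting in control and in knockout, and interaction. The test fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, called 4 in fasted against fed controls, 3 in fasted against fed knockouts and 0 in the others. The smallest adjusted p with an estimated correlation were 0.38, 0.96, 0.94, 0.088, 0.13 and 0.51 in the same order.

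The lists, tests, threshold, a first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule allowed Foxo3 and its paralogs, the 8 largest increases and 8 largest decreases among genes past the threshold with at least 1 CPM in a compared group, no overlap between the libraries of the 2 groups (not asked for the mean or the interaction) and a symbol that is not a provisional name, and the 4 members of each list with the smallest p. A gene chosen after its values were seen is named as such.

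This first set held RLE size factors, upper-quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1 after a filter of 0.5 TPM, a fit of only the compared groups, a replicate block, a minimum of 2-fold, camera with an estimated correlation, fry, and leaving out each library in turn. Alternatives added after seeing the data were protein-coding genes only, no mitochondrial genes, no fed control replicate 3 together with the replicate block, array quality weights, DESeq2 adjusted over the genes of the edgeR test, and camera on the ranked statistics of edgeR. DESeq2 with its own filter on mean counts gave an adjusted p to 3151 genes in the fed genotype comparison and to 15552 or more in the others. For the alternatives to the gene test, the lists were tested by camera on the ranked z values of each setting's gene test. Leaving out a library leaves 2 in its group, which are assumed to vary like the other groups.

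The gene test was tested on simulated data in which 100 genes were changed 2-fold and 100 genes 4-fold in counts simulated with the spread of these libraries. It recovered 64% and 86% of them in the fed genotype comparison, 63% and 90% in the fasted one, 78% and 97% for their mean, 54% and 89% for fasting in control, 54% and 91% for fasting in knockout, and 36% and 86% for the interaction, with between 5 and 11 false calls. These shares hold for data with that many changed genes, since the adjusted threshold is stricter where fewer genes change. A list of 20 genes shifted 1.5-fold was called by camera in all 6 comparisons. Of the 38 other lists, 0 were called, in data where genes vary independently.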

Results

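Liver RNA was sequenced from 12 male mice aged 16 to 18 months, with 3 animals in each of 4 groups. Control mice carried floxed Foxo3 alleles and no Cre. Knockout mice carried the same alleles together with albumin-promoter Cre, which is active in hepatocytes. Each genotype was sampled in the fed state and after an overnight fast. Foxo3 encodes a forkhead transcription factor that insulin signalling keeps out of the nucleus, and the series addresses the part it plays in the liver of ageing mice under both feeding states. The design gives 6 comparisons: fasted against fed in each genotype, knockout against control in each feeding state and averaged over both, and the interaction of genotype and fasting. No label names a batch or cohort, and the column numbers of the deposited tables run in blocks by group. Differences between cohorts or days can therefore not be separated from genotype or feeding in any of these comparisons. Library totals were 21420533, 22203047 and 19640018 counts in fed control and 19409644, 19164610 and 22414976 counts in fasted control livers. They were 20255766, 17520058 and 18744668 counts in fed knockout and 22009155, 22337097 and 18420882 counts in fasted knockout livers. Of 55487 annotated genes, 15862 had enough counts to be tested. Levels are given as CPM, counts scaled to a library of 1000000 (mean ± SD, n = 3 per group), and changes as log2 fold changes with the standard error (SE).

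Foxo3 transcripts were not lower in the libraries labelled knockout. In replicate order, Foxo3 stood at 45.5, 44.5 and 50.4 CPM in fed control livers and at 59.4, 58.8 and 62.2 CPM in fed knockout livers. In fasted livers it stood at 44.3, 39.9 and 38.1 CPM in controls and at 46.6, 53.6 and 53.4 CPM in knockouts. Every library labelled knockout was thus above every control library of the same feeding state, with a log2 difference of 0.36 in fed livers (SE 0.093, adjusted p = 0.68) and 0.33 in fasted livers (SE 0.093, adjusted p = 0.45). Averaged over both states the difference was 0.34 (SE 0.066, adjusted p = 0.25), which missed the threshold by edgeR and passed it by DESeq2. Foxo3 (ENSMUSG00000048756) spans positions 42181841 to 42276755 of chromosome 10 in build mm10. The labels do not name the floxed exons, and a gene-level count also takes reads from exons that are left in place, so it does not check the genotype label. "Knockout" here means the libraries labelled so. The paralog Foxo1 was at 46.1 ± 4.9 CPM in fed control, 59.5 ± 8 in fasted control, 49.2 ± 1 in fed knockout and 61.5 ± 11 in fasted knockout livers, and Foxo4 was between 26.4 and 29.1 CPM in all 4 groups. Neither differed past the threshold between genotypes (adjusted p = 0.96 and 0.97 in fed, 0.94 and 0.97 in fasted livers), and Foxo6, at no more than 0.142 CPM in any library, had too few counts to be tested.

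**Figure D1:**
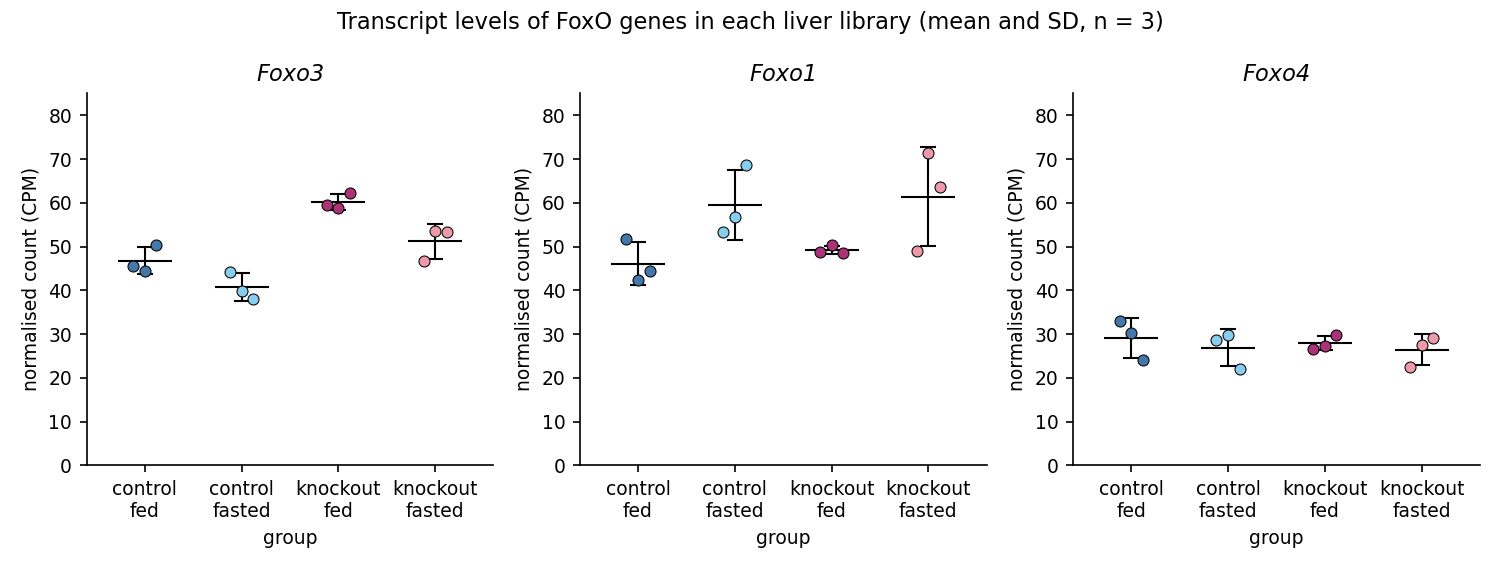
Normalised counts (CPM, vertical axis) of Foxo3, Foxo1 and Foxo4 in the 4 groups; each point is 1 library and the horizontal lines with bars are the mean and SD of 3 libraries. Foxo3 lies between 58.8 and 62.2 CPM in the fed libraries labelled knockout and between 44.5 and 50.4 CPM in the fed control libraries.

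The first principal component (25.3% of the variance) was positive in all 6 fed libraries (7.73 to 45) and negative in all 6 fasted libraries (-40.7 to -9.01). The second (17%) set fed control replicate 3 apart, at 52.2 against -27.5 to 20.3 for the remaining libraries. In that library, all 21 tested interferon response genes lay above the mean of the other fed control libraries (median log2 difference 2.2). So did all 17 cell cycle genes (1.5), 16 of 17 fibrosis and matrix genes (1.5), all 12 markers of infiltrating macrophages (1.7) and all 10 markers of T and NK cells (2.2). Male-biased liver genes were lower in it, with a median log2 difference of -1.3. The collagen gene Col1a1 reached 82.4 CPM there and no more than 17.6 CPM elsewhere. In fed knockout replicate 1, the serum amyloid genes Saa1 and Saa2, whose near-identical sequences make their counts uncertain, reached 2110 and 1840 CPM, against at most 328 and 94.4 CPM elsewhere. In fasted control replicate 3, the antibody genes Igha, Igkc and Jchain reached 1120, 551 and 199 CPM, against at most 12.7, 79.8 and 14.7 CPM elsewhere. These genes, apart from Igkc and Jchain, were picked out after their values were seen.

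In control livers, overnight fasting lowered genes of fatty acid synthesis and raised genes of fatty acid oxidation, ketogenesis and gluconeogenesis. Of 18 tested genes of fatty acid synthesis, 14 fell (15 adjusted over the list alone, camera adjusted p = 5.4e-22, adjusted p = 0.088 with an estimated correlation). Fasn, which encodes fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), was 9.84-fold lower, at 1890 ± 650 CPM in fed and 192 ± 39 CPM in fasted controls (log2 fold change -3.30, SE 0.3, adjusted p = 0.00019). Acly, which supplies cytosolic acetyl-CoA, changed by -2.05 (SE 0.21, adjusted p = 0.0003). The acetyl-CoA carboxylase genes Acaca and Acacb changed by -1.73 and -2.36, and the lipogenic gene Thrsp by -3.96. Pnpla3, also lipogenic, was at 3.28, 7.39 and 7.63 CPM in fed controls and at 0, 0.0566 and 0.38 CPM in fasted controls. Its fitted change of -5.21 was -7.54 without fasted control replicate 3. Of 24 genes of fatty acid oxidation and ketogenesis, 14 rose (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.7e-15, adjusted p = 0.48 with an estimated correlation). Cpt1a, which encodes the enzyme that commits long-chain fatty acids to mitochondrial oxidation (ENSMUSG00000024900, chromosome 19, 3322334 to 3385733), rose from 497 ± 37 to 930 ± 53 CPM (log2 fold change 0.90, SE 0.12, adjusted p = 0.002). The oxidation enzymes Cpt2, Acadm and Hadhb rose by 0.86, 0.88 and 0.89 on the log2 scale. Of 12 gluconeogenic genes 3 rose, and 3 did so adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.48 with an estimated correlation). Among them Pck1, encoding cytosolic PEP carboxykinase (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), rose from 1710 ± 290 to 3940 ± 270 CPM (1.21, SE 0.23, adjusted p = 0.013). Of 15 genes of glycolysis and glucose uptake 2 fell (3 adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.48 with an estimated correlation). They include Pklr, liver pyruvate kinase (-2.17, adjusted p = 0.018).

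Further lists passed the camera threshold in fasted control livers. Of 20 genes of amino acid breakdown and the urea cycle, 4 rose (9 adjusted over the list alone, camera adjusted p = 3.1e-05, adjusted p = 0.92 with an estimated correlation). They include Cth, a cysteine-forming enzyme of transsulfuration (1.19, adjusted p = 0.02), and Asl, argininosuccinate lyase (1.10, adjusted p = 0.026). Of 11 heat shock genes, 4 rose (7 adjusted over the list alone, camera adjusted p = 9.8e-06, adjusted p = 0.5 with an estimated correlation). Hspa1b was at 2.81 ± 0.59 CPM in fed and 15.1 ± 2.5 CPM in fasted controls (2.42, SE 0.43, adjusted p = 0.012). Of 22 genes of cholesterol synthesis, 2 fell (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00023, adjusted p = 0.92 with an estimated correlation). These were Sc5d (-1.24, adjusted p = 0.0037) and Insig1 (-1.14, adjusted p = 0.012). Fibrosis and stellate cell genes were lower on balance (camera adjusted p = 0.0097 and 0.0055, adjusted p = 0.92 for both with an estimated correlation). They had 0 of 17 and 0 of 12 members past the threshold by edgeR, against 7 and 3 at an unadjusted p under 0.05 and 4 and 1 by DESeq2. Fed control replicate 3 held high fibrosis genes, and without it the fibrosis list missed the threshold (adjusted p = 0.24). Of 24 insulin-suppressed and FoxO target genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone). The list did not move as a whole (camera adjusted p = 0.71, median 0.035, mean -0.029, test upward). Klf15, a fasting-responsive transcription factor, rose by 0.84 (adjusted p = 0.0089), and Gadd45a, a growth arrest gene, changed by -2.10 (adjusted p = 0.0012). The clock genes Bhlhe40 and Per1 changed by -0.88 and 0.78 (adjusted p = 0.0017 and 0.0077). Plin5, a lipid droplet protein of oxidative tissues, rose by 1.17 (adjusted p = 0.0017). Chrna4, a nicotinic acetylcholine receptor subunit, was 41.7-fold lower (adjusted p = 0.00015).

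Across all genes, 657 passed the threshold between fasted and fed control livers, 325 higher and 332 lower, of which 90 and 141 changed at least 2-fold (edgeR). DESeq2 gave 543 higher and 627 lower. The total was 433 without fed control replicate 1, 341 without fed control replicate 2, 538 without fed control replicate 3 (207 of them higher), 272 without fasted control replicate 2 and 312 without fasted control replicate 3. Calls that ended without 1 library were those of Hspa1b (fed control replicate 2, adjusted p = 0.053), Tat (fasted control 3, 0.087), Insig1 (fasted control 2 or 3, up to 0.059) and Pklr (fed control 2, fasted control 1 or 3, up to 0.076). The same held for Cth (fed control 2 or 3, fasted control 2 or 3, up to 0.078) and Asl (fed control 1 or 3, fasted control 2 or 3, up to 0.1). Among lists it held for cholesterol synthesis (fasted control 3, 0.055) and stellate cells (fed control 3, fasted control 2 or 3, up to 0.14).

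In knockout livers, fasting lowered genes of fatty acid and cholesterol synthesis and raised genes of fatty acid oxidation and ketogenesis. Of 24 genes of fatty acid oxidation and ketogenesis, 18 rose (22 adjusted over the list alone, camera adjusted p = 6.6e-34, adjusted p = 0.13 with an estimated correlation). Cpt1a rose by 1.06 (SE 0.12, adjusted p = 0.0014) and Bdh1, which interconverts the ketone bodies, by 0.96 (SE 0.13, adjusted p = 0.0028). Of 18 genes of fatty acid synthesis, 11 fell (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.1e-15, adjusted p = 0.13 with an estimated correlation). Fasn was 9.06-fold lower (1540 ± 430 to 170 ± 36 CPM, adjusted p = 0.00071), and Acly and Acaca changed by -1.99 and -1.40. Of 22 cholesterol synthesis genes, 5 fell (15 adjusted over the list alone, camera adjusted p = 1e-16, adjusted p = 0.32 with an estimated correlation). Insig1, a sterol-sensing regulator of this pathway (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662), went from 586 ± 130 to 189 ± 36 CPM (-1.63, SE 0.22, adjusted p = 0.0028). Sc5d changed by -1.31 (adjusted p = 0.0041). Of 17 lipid droplet genes, 5 rose (9 adjusted over the list alone, camera adjusted p = 2.9e-08, adjusted p = 0.3 with an estimated correlation). Plin5 (1.15, adjusted p = 0.0028) and the lipase gene Mgll (1.2, adjusted p = 0.01) were among them. Of 14 male-biased liver genes, 5 fell (7 adjusted over the list alone, camera adjusted p = 2.9e-08, adjusted p = 0.32 with an estimated correlation). The complement gene C6 changed by -1.99 (adjusted p = 0.02) and Nudt7, a peroxisomal CoA hydrolase, by -1.63 (adjusted p = 0.017). Of 13 female-biased genes, 2 rose (5 adjusted over the list alone, camera adjusted p = 9e-05, adjusted p = 0.32 with an estimated correlation). Acot3, whose count is uncertain because its family members are similar, rose by 3.14 (adjusted p = 0.027).

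The gluconeogenic list did not pass in knockout livers, with 1 of 12 genes higher (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.67, median 0.12, mean -0.092, test upward). Pck1 stood at 2560 ± 380 CPM in fed and 4020 ± 1300 CPM in fasted knockout livers (0.65, SE 0.23, adjusted p = 0.19). Tat, tyrosine aminotransferase, stood at 1670 ± 360 and 1130 ± 100 CPM (-0.57, SE 0.19, adjusted p = 0.15). Chrna4 was 47.9-fold lower (adjusted p = 0.00045) and Bhlhe40 changed by -0.92 (adjusted p = 0.0021). Abcb4, a phospholipid exporter of the bile canaliculus, rose by 1.2 (adjusted p = 0.009). The cell cycle list was lower on balance (camera adjusted p = 0.021, adjusted p = 0.7 with an estimated correlation), with 0 of 17 members past the threshold by edgeR, 1 at an unadjusted p under 0.05 and 0 by DESeq2. Of the remaining 9 lists past the camera threshold, each missed it without at least 1 library, and B and plasma cells (lower, 0.049) also with all libraries on the ranked edgeR statistic used for those fits (0.071). Oxidative phosphorylation (higher, 0.0012) did so without fasted knockout replicate 1 (0.054) and heat shock genes (higher, 0.0077) without fasted knockout replicate 3 (0.21). In all, 393 genes passed between fasted and fed knockout livers, 215 higher and 178 lower, with 72 and 93 changed at least 2-fold (edgeR). DESeq2 gave 398 higher and 393 lower. The total was 88, 160 and 218 without fed knockout replicates 1, 2 and 3, 157, 238 and 148 without fasted knockout replicates 1, 2 and 3, and 573 without fed control replicate 3, which enters through the shared estimate of spread. C6 missed the threshold without fed knockout 1 or 2 or fasted knockout 3 (up to 0.086). So did Nudt7 without fed knockout 1 or 3 or fasted knockout 1 or 3 (up to 0.078), and Acot3 without any 1 of the 6 knockout libraries (up to 0.083).

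**Figure D2:**
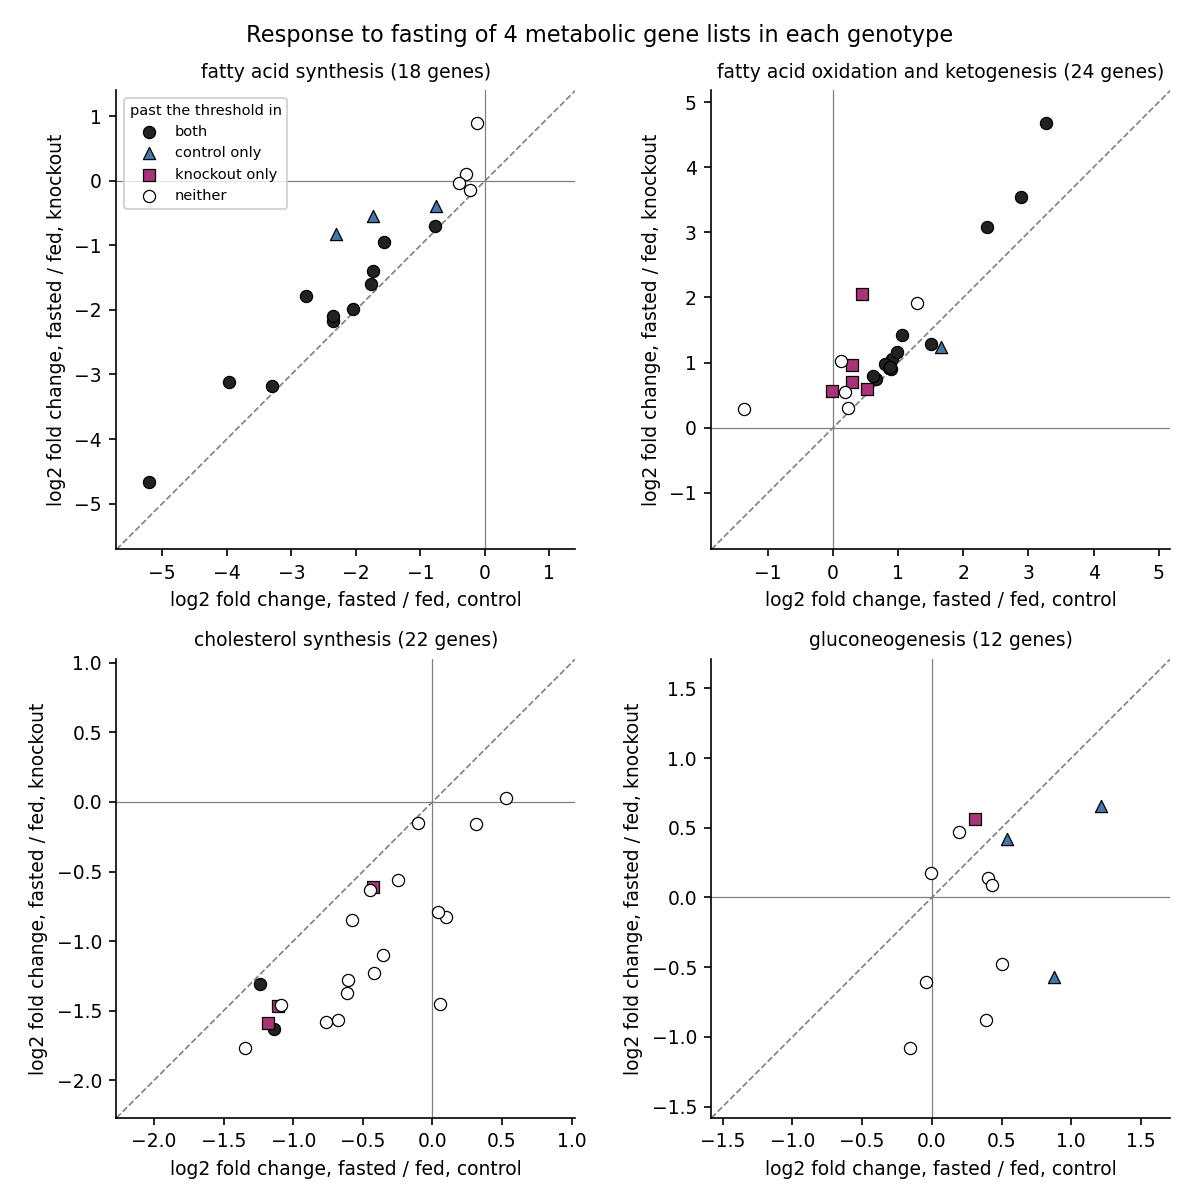
Log2 fold change of fasted over fed livers in control (horizontal axis) and knockout (vertical axis) for the tested genes of 4 lists; each point is 1 gene, its shape shows in which genotype it passed the threshold, and the dashed line marks equal changes. All 22 cholesterol synthesis genes lie below that line, all 18 fatty acid synthesis genes lie above it, and Fasn is at -3.30 and -3.18.

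The responses of the 2 genotypes to fasting overlapped. Of the genes that rose, 107 were shared (4.4 expected by chance), and of those that fell, 91 were shared (3.7 expected), with 0 called in opposite directions by edgeR. Of the 852 genes called in at least 1 genotype, 782 (91.8%) changed in the same direction in both. Across all 15862 genes, which are not independent replicates, the log2 fold changes had r = 0.35 and rho = 0.36. Of the 459 genes called in control livers only, 407 had the same sign in knockout livers, and 1 of the 459, Rpl29, passed the test of the interaction. Of the 195 called in knockout livers only, 177 had the same sign in controls and 0 passed the interaction test by edgeR, in which 1141 of all genes had an unadjusted p under 0.05 and DESeq2 called 60.

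In fed livers, knockout and control differed in the balance of several gene lists, while edgeR called 0 single genes (970 at an unadjusted p under 0.05). DESeq2 called 35 of the 3151 genes that its own filter left in this comparison, and 31 when adjusted over 15837 of the genes edgeR tested. Genes of fatty acid oxidation and ketogenesis were lower in knockout livers, 23 of 24 of them (median log2 difference -0.30, camera adjusted p = 8.3e-15, adjusted p = 0.38 with an estimated correlation). Acute phase genes, encoding plasma proteins that the liver secretes in inflammation, were higher, 17 of 18 (median 1, camera adjusted p = 2.2e-12, adjusted p = 0.41 with an estimated correlation). All 17 lipid droplet genes were lower (median -0.49, camera adjusted p = 2.2e-10, adjusted p = 0.38 with an estimated correlation). All 14 male-biased genes were higher (median 0.79, camera adjusted p = 4.2e-09) and 11 of 13 female-biased genes lower (median -1.9, camera adjusted p = 0.00076), with adjusted p = 0.38 and 0.52 with an estimated correlation. By edgeR, 0 members of each of these lists passed over all genes. At an unadjusted p under 0.05 there were 11 lower oxidation, 11 higher acute phase, 9 lower lipid droplet, 2 higher male-biased and 6 lower female-biased genes. In the same order DESeq2 called 3, 3, 1, 1 and 1 of the 22, 15, 10, 9 and 2 members that its filter left, and 2, 1, 0, 0 and 0 when adjusted over the genes of the edgeR test. Adjusted over the list alone the edgeR counts were 4, 3, 3, 0 and 0. Without fed knockout replicate 1, the library with the high serum amyloid values, the acute phase median was 0.62. Without fed control replicate 3, in which male-biased genes were low, the male-biased median was 0.52 (camera adjusted p = 0.0055) and the female-biased one -0.92 (0.013). Without fed control replicate 2 the male-biased and lipid droplet medians were 1.3 and -0.76.

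Among the members, DESeq2 called Bdh1, Plin2, Hpx and Hp after its own filter, and of these Hpx when adjusted over the genes of the edgeR test. Over all genes edgeR called none of the members named here. Bdh1 was at 243 ± 21 CPM in fed control and 177 ± 27 CPM in fed knockout livers (-0.46, SE 0.13, adjusted p = 0.68). Plin2, the main coat protein of liver lipid droplets, was at 651 ± 230 and 362 ± 75 CPM (-0.84, SE 0.23, adjusted p = 0.68). The fatty acid carrier gene Cd36 was at 204 ± 93 and 108 ± 22 CPM (-0.92, SE 0.29, adjusted p = 0.78). Without fed control replicate 3 the differences of Plin2 and Cd36 were -0.56 and -0.52. Hemopexin (Hpx) was at 2400 ± 230 and 5640 ± 2100 CPM (1.23, SE 0.32, adjusted p = 0.68). Haptoglobin (Hp) was at 2190 ± 320 and 4770 ± 1100 CPM (1.13, SE 0.35, adjusted p = 0.78). The smallest adjusted p over all genes was 0.13. It belonged among others to Irs2, an insulin receptor substrate and FoxO target (ENSMUSG00000038894, chromosome 8, 10984681 to 11008458), with 15.1 ± 0.81 CPM in control and 31.1 ± 7.5 CPM in knockout livers (1.05, SE 0.16). Tsc22d3, a glucocorticoid-induced gene (0.89), and Fst, encoding follistatin (1.5), had the same adjusted p and are named after their values were seen. Tat was at 771 ± 150 and 1670 ± 360 CPM (1.12, SE 0.19, adjusted p = 0.17). Irs2, Tsc22d3, Fst and Tat passed the threshold with no filter on low counts and by DESeq2 adjusted over the genes of the edgeR test. By DESeq2 with its own filter Tsc22d3 and Tat did, and with array quality weights Tsc22d3 and Fst did. The FoxO target list as a whole did not differ past the threshold (camera adjusted p = 0.76). It had 0 of 24 members called by edgeR, 3 higher and 3 lower at an unadjusted p under 0.05, and 0 by DESeq2 among the 9 that its filter left. Irs2 was the 1 member called by DESeq2 adjusted over the genes of the edgeR test and by edgeR adjusted over the list alone.

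Markers of other cells moved as well in fed livers. All 12 stellate cell markers were lower in knockout livers (median -0.62, camera adjusted p = 3.9e-07) and 6 of 7 neutrophil markers higher (median 1.4, camera adjusted p = 0.00086), both with adjusted p = 0.52 with an estimated correlation. Of either list, edgeR called 0, with 1 and 3 at an unadjusted p under 0.05. DESeq2 called 0 too, but its filter left only 4 and 1 of their members, and adjusted over the genes of the edgeR test it called 0. The 12 stellate markers include Lrat, at 33.1 ± 18 CPM in control and 16.3 ± 8.9 CPM in knockout livers (-1.02, SE 0.49, adjusted p = 0.81). Fed control replicate 3 held 11 of the 12 stellate markers above the mean of the other fed controls (median 0.75) and 53.3 CPM of Lrat. Without it the list median was -0.36 (camera adjusted p = 0.0066) and Lrat differed by -0.50. With the replicate block as well, the list missed the threshold (0.053). Without fed knockout replicate 1 the values were -0.4 and -0.62. The neutrophil markers include S100a8, at 0.865 ± 0.29 and 2.34 ± 0.84 CPM (1.43, SE 0.53, adjusted p = 0.81). Of 39 lists, 15 passed the camera threshold in fed livers, 7 of them in every fit that left out 1 library. Others did not hold in all. Fatty acid synthesis (lower, 0.00037) missed it without fed control replicate 2 (0.093) and amino acid breakdown and urea cycle (higher, 6.2e-05) without fed control replicate 3 (0.14). Periportal genes (higher, 0.00035) missed it without fed knockout replicate 1 (0.13), the library with the high serum amyloid values. Over all 15862 genes, edgeR called 0 between fed knockout and fed control livers, with 970 at an unadjusted p under 0.05 (793 expected by chance). Here limma-voom called 0, DESeq2 called 15 higher and 20 lower among its 3151 genes and 18 and 13 adjusted over the genes of the edgeR test, edgeR with no filter on low counts called 5, and edgeR without fed control replicate 1 called 1.

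In fasted livers, 5 genes passed between knockout and control, 4 higher and 1 lower in knockout livers. Rpl29, a protein of the large ribosomal subunit (ENSMUSG00000048758, chromosome 9, 106429454 to 106431568), was 15.8-fold higher, at 4.46 ± 1.4 CPM in control and 69.9 ± 19 CPM in knockout livers (log2 fold change 3.98, SE 0.25, adjusted p = 3.6e-05). Acpp, encoding the prostatic form of acid phosphatase (ENSMUSG00000032561, chromosome 9, 104288251 to 104337748), was at 0.186 ± 0.097 and 10.2 ± 4.9 CPM (5.68, SE 0.59, adjusted p = 0.011). Tdg, thymine DNA glycosylase of base excision repair (ENSMUSG00000034674, chromosome 10, 82629828 to 82650799), was 3.27-fold lower, at 9.61 ± 3.4 and 2.95 ± 0.83 CPM (-1.71, SE 0.24, adjusted p = 0.031). The remaining calls, Gm6344 (4.09, adjusted p = 0.014) and Gm10709 (2.01, adjusted p = 0.04), were named after their values were seen. Both are among 35 near-identical copies of Rpl29 in the genome, and Tdg has 5 such copies. In fed livers Rpl29 was at 86.8 ± 7.4 CPM in control and 87.1 ± 11 CPM in knockout animals, so the low values were those of the 3 fasted control libraries (4.1, 6 and 3.29 CPM). Fewer than 16 genes met the rule for naming by size of change.

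**Figure D3:**
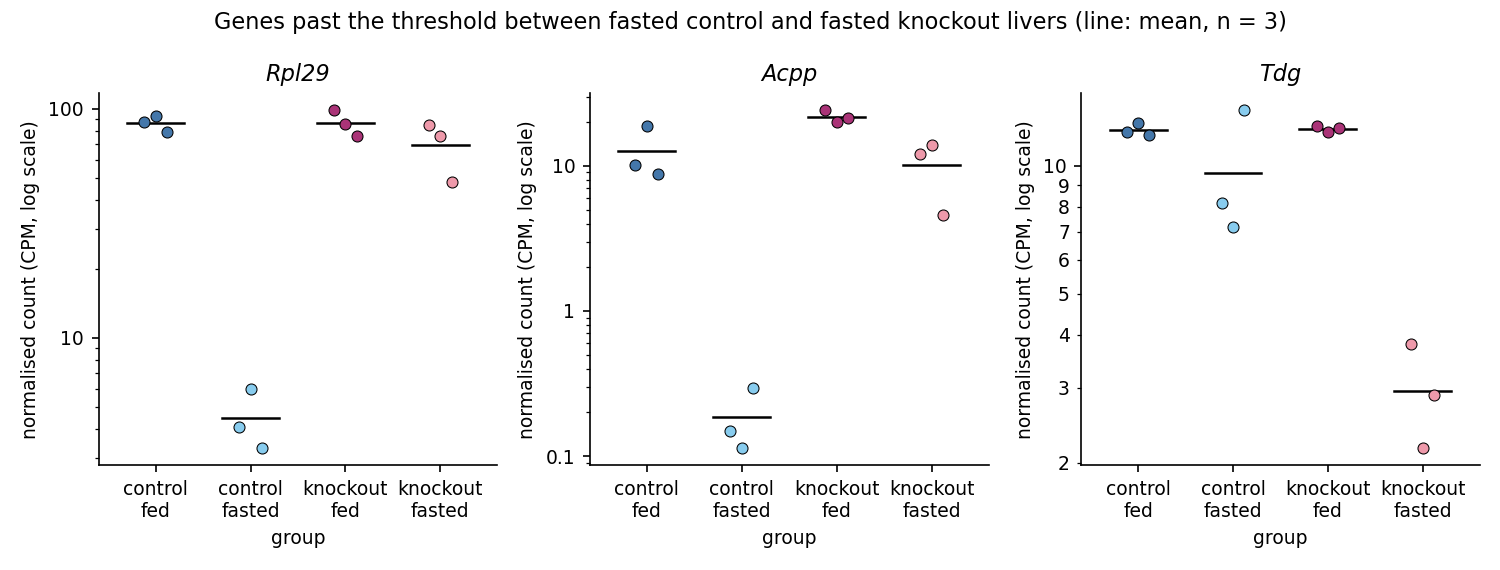
Normalised counts (CPM, vertical axis on a log scale) of Rpl29, Acpp and Tdg in the 4 groups; each point is 1 library and the line is the mean of 3. Rpl29 lies between 3.29 and 6 CPM in fasted control livers and between 48.2 and 98.6 CPM in all other libraries.

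Lymphocyte markers were lower in fasted knockout than in fasted control livers. All 9 B and plasma cell genes were lower (median -1.5, camera adjusted p = 0.00031, adjusted p = 0.96 with an estimated correlation). The count past the threshold was 0 by edgeR over all genes, 6 adjusted over the list alone and 0 by DESeq2, with 7 at an unadjusted p under 0.05. Igkc, the kappa light chain constant region, was at 205 ± 300 CPM in control and 12.7 ± 5.5 CPM in knockout livers (-4.01, SE 1.2, adjusted p = 0.51), and fasted control replicate 3 held 551 CPM of it. The B cell receptor gene Cd79a was at 2.09 ± 1.8 and 0.744 ± 0.14 CPM (-1.51, SE 0.55, adjusted p = 0.52), and that library held 4.13 CPM of it. Without it the list median was -0.55 (camera adjusted p = 0.043), and Igkc and Cd79a differed by -1.31 and -0.55. Of 10 T and NK cell genes, 9 were lower (median -1.2, camera adjusted p = 0.0014, adjusted p = 0.96 with an estimated correlation, 0 by edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 by DESeq2). Of 22 cholesterol synthesis genes, 20 were lower (median -0.32, camera adjusted p = 0.0026, adjusted p = 0.96 with an estimated correlation, 0 by edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 by DESeq2). The regulator Srebf2 was at 77.8 ± 7.2 and 59.8 ± 19 CPM (-0.38, SE 0.17, adjusted p = 0.55). That list missed the threshold without fasted control replicate 1 or fasted knockout replicate 1 or 3 (up to 0.91), with medians of -0.062, -0.14 and -0.18. Its median was -0.48 without fasted control replicate 3 and -0.72 without fasted knockout replicate 2, and Srebf2 differed by -0.66 without the latter and by -0.25 without fasted knockout replicate 3. The FoxO target list again did not differ past the threshold (camera adjusted p = 0.91, median 0.01, mean -0.03, test downward, 0 of 24 by edgeR and by DESeq2, 3 at an unadjusted p under 0.05). Male-biased genes, higher in fed knockout livers, were lower in fasted ones, 12 of 14 (median -0.79, camera adjusted p = 0.016, adjusted p = 0.96 with an estimated correlation, 0 by edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2). They missed the threshold without fasted control replicate 3 (median -0.49, 0.093) or fasted knockout replicate 1 (0.2). Amino acid breakdown and urea cycle genes, also higher in fed knockout livers, were lower here, 17 of 20 (0.019, adjusted p = 0.96 with an estimated correlation, 0 by edgeR, 3 at an unadjusted p under 0.05, 0 by DESeq2), and missed it without fasted control 2 or 3 or fasted knockout 2 (up to 0.35). In all, 8 lists passed the camera threshold. The other 3, all lower, missed it without several single libraries: gluconeogenesis (0.034) without fasted control 3, fed knockout 3 or fasted knockout 2 or 3 (up to 0.37), heat shock (0.02) without fasted control 2 or 3, fed knockout 3 or fasted knockout 1 or 2 (up to 0.4), and Kupffer cells (0.031) without fasted control 1, fed knockout 3 or fasted knockout 1 or 2 (up to 0.84). The call of Rpl29 held without any 1 library. Acpp missed it without any 1 of the fasted control replicates (up to 0.12), Gm6344 without fasted control 3 or fasted knockout 1 or 2 (up to 0.21; its change was 4.91 without fasted control 2), and Gm10709 without any 1 library but fed control 3 and fed knockout 3 (up to 0.39). Tdg missed it without fed control 1 or 2, fasted control 3, any fed knockout replicate or fasted knockout 2 or 3 (up to 0.13). Over all genes, 1429 had an unadjusted p under 0.05 and DESeq2 called 26 higher and 15 lower. The edgeR count was 1 gene without fasted control replicate 3 and 3 genes without fed control 1 or 2, fasted control 2, fed knockout 1 or 2, or any fasted knockout replicate.

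**Figure D4:**
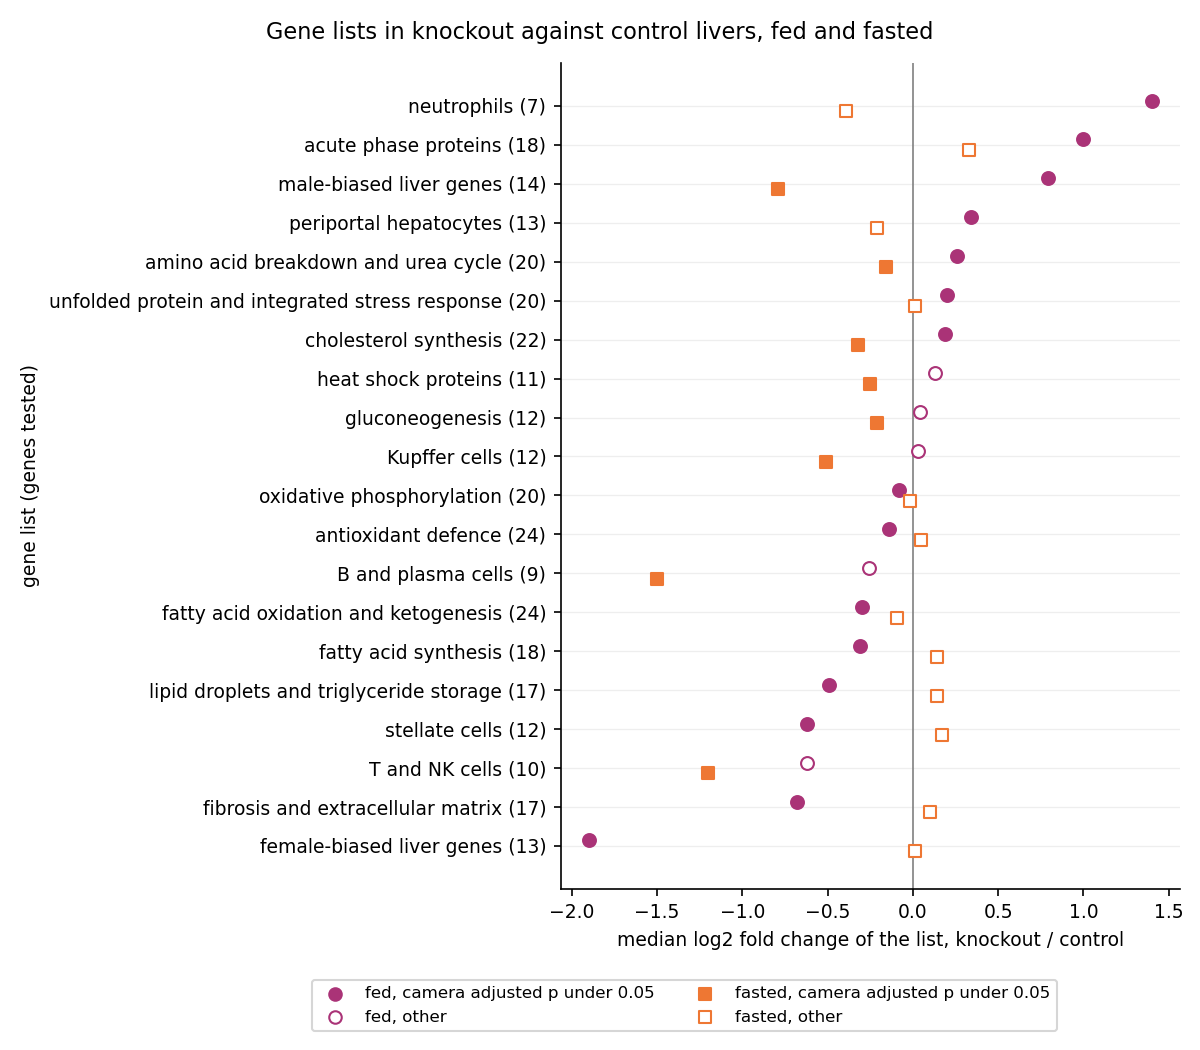
Median log2 fold change of knockout over control livers (horizontal axis) for the gene lists past the camera threshold in fed or fasted livers, with the number of tested genes in brackets; circles are fed and squares fasted comparisons, filled where the camera adjusted p was under 0.05. Acute phase genes stand at 1 in fed livers, and B and plasma cell genes at -1.5 in fasted livers.

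Averaged over fed and fasted livers, oxidation genes were lower on balance and acute phase genes higher in knockout livers. Of 100 splits of the libraries, the real one included, 98 gave at least as many lists as the 6 that passed camera here. Chance is thus not excluded for these list calls. Of 24 genes of fatty acid oxidation and ketogenesis, 23 were lower (median -0.20, camera adjusted p = 7.4e-09, adjusted p = 0.94 with an estimated correlation). Of these, 0 passed by edgeR, 4 adjusted over the list alone, 9 at an unadjusted p under 0.05 and 2 by DESeq2. Among them Ehhadh, the bifunctional enzyme of peroxisomal oxidation, had a log2 difference of -0.77 (SE 0.21, adjusted p = 0.48), which DESeq2 called. Of 18 acute phase genes, 17 were higher (median 0.58, camera adjusted p = 7.1e-08, adjusted p = 0.94 with an estimated correlation). Of these, 0 passed by edgeR, 0 adjusted over the list alone, 12 at an unadjusted p under 0.05 and 0 by DESeq2. In fasted livers alone neither list passed, with 18 of 24 oxidation genes lower (median -0.095, camera adjusted p = 0.28) and 14 of 18 acute phase genes higher (median 0.33, 0.4). Both had interactions past the camera threshold (4.2e-05 and 5.1e-05, adjusted p = 0.53 for both with an estimated correlation). Ceruloplasmin (Cp) differed by 0.47 (SE 0.15, adjusted p = 0.56). The other 4 lists past the camera threshold were lower, each with adjusted p = 0.94 with an estimated correlation and 0 members called by edgeR or by DESeq2. All 9 B and plasma cell genes were lower (median -0.95, camera adjusted p = 0.0006, 5 at an unadjusted p under 0.05), with a median of -0.37 without fasted control replicate 3. All 10 T and NK cell genes were lower (median -0.94, 0.0047, 3 unadjusted), with a median of -0.42 without fed control replicate 3, where the list missed the threshold (0.16). Of 17 lipid droplet genes 15 were lower (0.0041, 2 unadjusted), a call that ended without fed control replicate 3 or fed knockout replicate 1 (up to 0.15). All 12 stellate cell genes were lower (0.029, 1 unadjusted), a call that ended on the ranked edgeR statistic (0.075). The clock gene Bhlhe40 differed by 0.43 (SE 0.08, adjusted p = 0.25) and was called by DESeq2. Genes past the threshold were Rpl29 (1.99, SE 0.16, adjusted p = 0.00062) and Acpp (3.23, SE 0.36, adjusted p = 0.019), both higher. There were 1255 genes at an unadjusted p under 0.05 and 27 higher and 19 lower by DESeq2. Acpp missed the threshold without any 1 of fed control 1 or 3, the fasted control and fed knockout replicates, or fasted knockout 1 (up to 0.17). The count was 3 without fasted knockout 2 and 1 without fasted control 2 or 3, any fed knockout replicate or fasted knockout 1. Only 2 genes, fewer than 16, met the rule for naming. The log2 differences between knockout and control in fed livers did not correlate with those in fasted livers (r = -0.068, rho = 0.023). This was taken across the 15862 genes, which are not independent replicates. With 0 genes called by edgeR in fed and 5 in fasted livers, few differences stood clear of their error. The correlation therefore does not show that the effects are unrelated.

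The interaction asks whether the response to fasting differed between the genotypes. Rpl29 alone passed by edgeR, with a log2 difference between the responses of 3.98 (SE 0.32, adjusted p = 0.00064). It was 19.6-fold lower in fasted than in fed controls (-4.29, SE 0.25, adjusted p = 1.7e-05) and changed by -0.32 in knockout livers (SE 0.21, adjusted p = 0.55). Acpp fell by 5.98 on the log2 scale in controls (SE 0.59, adjusted p = 0.00099) against -1.10 in knockouts (adjusted p = 0.19). Its interaction of 4.89 (SE 0.73, adjusted p = 0.15) passed by DESeq2 and without fasted knockout replicate 3. Lipid droplet genes had a more positive response in knockout livers, 14 of 17 (median 0.51, camera adjusted p = 1.2e-06, adjusted p = 0.51 with an estimated correlation, 0 by edgeR, 6 adjusted over the list alone, 9 at an unadjusted p under 0.05, 2 by DESeq2). Cd36 went from 204 ± 93 to 148 ± 18 CPM in controls and from 108 ± 22 to 249 ± 47 CPM in knockouts (1.67, SE 0.4, adjusted p = 0.52), an interaction that DESeq2 called. Male-biased genes had a more negative response, 13 of 14 (median -1.7, camera adjusted p = 6.3e-08, adjusted p = 0.51 with an estimated correlation, 0 by edgeR, 2 adjusted over the list alone, 7 at an unadjusted p under 0.05, 1 by DESeq2). Male-biased genes were low in fed control replicate 3. Without it the median interaction was -1.2 (camera adjusted p = 0.00012), and the median response to fasting in controls was -0.42 instead of -0.038. The latter was also 0.085 without fed control replicate 2 and -0.29, 0.043 and -0.12 without fasted control replicates 1, 2 and 3, so its sign is not settled. Amino acid breakdown and urea cycle genes did so too, 18 of 20 (median -0.46, camera adjusted p = 3.6e-06, adjusted p = 0.51 with an estimated correlation, 0 by edgeR, 0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by DESeq2). Their median was -0.21 without fed control replicate 3 and -0.3 without fed knockout replicate 1. Arg1, arginase of the urea cycle, had an interaction of -0.79 (SE 0.25, adjusted p = 0.57). Tat rose by 0.88 in controls (adjusted p = 0.021; 0.087 without fasted control replicate 3), against -0.57 in knockouts (adjusted p = 0.15). Its interaction of -1.45 (SE 0.27, adjusted p = 0.2) was called by DESeq2 and with no filter on low counts. Fasn and Cpt1a had interactions of 0.12 and 0.16 (adjusted p = 0.97 and 0.91), which without single libraries lay between -0.155 and 0.374 and between 0.0855 and 0.243. The FoxO target list did not pass (camera adjusted p = 0.98, median -0.073, mean 0.012, test downward). Of 39 lists, 19 passed the camera threshold. Of these, T and NK cells missed it with all libraries on the ranked edgeR statistic used for the fits without 1 library (0.16), and 7 others missed it without at least 1 library. Over all genes, 1141 had an unadjusted p under 0.05 and DESeq2 called 37 higher and 23 lower. The edgeR count was 2 genes without fed control 1 or fasted control 1 or 2 and 3 without fasted knockout 3, and 1 gene met the rule for naming.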

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

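The tests of gene copies, of the chromosome segment and of the library that stands apart were chosen after the results were seen; the tests of the fed knockout lists against single libraries and all splits of the libraries were written before.

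Rpl29 and Acpp, both on chromosome 9, were low in the 3 fasted control libraries and Tdg in the 3 fasted knockout libraries, and for Rpl29 the interaction of genotype and fasting passed (adjusted p = 0.00064). A shift of reads to the 35 near-identical copies of Rpl29 would leave the summed CPM of the family unchanged, but it was 2.88-fold higher in fasted knockout than in fasted control livers (95% interval 1.9 to 4.3). This is above the 1.5-fold limit set for that explanation and below the 3-fold set to exclude it. The sum was 40 ± 6.6 CPM in fasted control livers, against 131 ± 12 in fed control and 115 ± 21 in fasted knockout livers. Rpl29 alone stood at 4.46, 86.8 and 69.9 CPM in the same order, so the copies together did not gain what Rpl29 lost. These values argue against a shift to copies whose reads were counted. Reads that match several copies could be uncounted, and that possibility stays open. A segment around Rpl29 inherited differently by the fasted control animals is a candidate explanation. Within 2 Mb on either side, 22 of 77 genes (28.6%) had an unadjusted p under 0.05 in the fasted comparison, against 9% of all genes. Fisher's exact test (2-sided) gave p = 6.7e-07, adjusted over 6 comparisons 4e-06. That share was reached by 0.08% of 12519 windows elsewhere, whereas in fed livers it was 7 of 77. The genes were measured in the same animals and the windows overlap, so neither are independent units. Neither the p-value nor the 0.08% therefore measures variation between animals. For Tdg, the sum over the gene and its 5 copies differed by -0.43 (log2, 95% interval -0.94 to 0.071), against -1.7 for Tdg alone, so assignment of reads between copies may account for that call, while effects of genotype and fasting on these genes stay open.

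Fed control replicate 3 stood apart from the other fed control libraries, with 200 genes more than 2-fold above both of them, against at most 51 in any other library. Depth does not explain this: after thinning all libraries to the lowest total the count was 195, against at most 56. A smaller share of hepatocytes alone would raise the markers of all other cell types alike. The medians of T and NK cell markers (2.2, SE 0.34) and of B and plasma cell markers (-0.2, SE 0.34) lay 2.4 apart, or 5 standard errors. This argues against a smaller share as the only cause. The 2 lists were picked as the highest and lowest, so the 5 standard errors overstate the gap. Left out of the comparison were erythroid cells (median -0.23, SE 0.069, 0 of 6 genes higher) and adipocytes (0.52, SE 0.98). Medians of the remaining lists compared were all above 0, from 0.24 (cholangiocytes) to 1.7 (infiltrating macrophages). A smaller share together with another change is thus not argued against. A fasted or female animal under this label is argued against too, since its fatty acid synthesis genes stood at the fed level (position 1 on a scale from 0 in fasted to 1 in the other fed controls) and Xist did not exceed 0.323 CPM in any library. What set this animal apart stays open, and no biological explanation beyond these was tested.

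In fed livers, genes of fatty acid oxidation, lipid droplets, acute phase proteins and male-biased expression differed on balance between knockout and control. These 4 lists were those with the smallest camera p in this comparison, so their hold does not extend to the other lists. All 4 kept their direction and passed in each of the 6 fits without 1 fed library. A single library is thus not the whole source for these 4, while of the 15 lists called, 7 passed in every fit without 1 library. The size of the 4 moved. The acute phase median was 0.62 instead of 1 without fed knockout replicate 1. The male-biased median was 0.52 instead of 0.79 without fed control replicate 3 (camera adjusted p = 0.0055). Without fed control replicate 2 the male-biased and lipid droplet medians were 1.3 and -0.76 (instead of -0.49). Correlation between genes is not set aside, since with an estimated correlation the adjusted p were 0.38 to 0.41. Of the 10 splits of the 6 fed libraries, 7 gave as many lists as the real one (15 lists, highest other 21), and 10 splits are too few for a share under 0.05. The genotype named by the design and differences between animals or cohorts, which no label separates from it, cannot be told apart here.

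Other splits of the same libraries were also counted for the remaining results. Between fed knockout and fed control, the real split gave 0 called genes by edgeR (970 at an unadjusted p under 0.05, 35 by DESeq2 among the 3151 genes that its filter left), as did all 10 splits (highest other 0). In fasted knockout against fasted control, 1 of the 10 splits, the real one, gave 5 genes (highest other 3), and 7 of the 10 gave 8 lists or more (highest other 24). Fasting in control gave 657 genes (1 of the 10 splits, highest other 2) and 9 lists (10 of the 10 splits, highest other 21), and fasting in knockout 393 genes (1 of the 10 splits, highest other 0) and 16 lists (4 of the 10 splits, highest other 21). In these comparisons the 10 splits are too few for a share under 0.05. For the mean of both feeding states, 5 of the 100 splits drawn gave 2 genes or more (highest other 9) and 98 gave 6 lists or more (highest other 25), so chance is not excluded. For the interaction, 18 of the 100 splits gave at least 1 gene (highest other 6). Of the same 100, 13 gave 19 lists or more (highest other 24). List calls with the preset correlation are thus common in splits that mix the groups. Some of the 100 splits, however, kept the fasted groups whole or exchanged them whole and mixed only fed libraries. These keep the fasted difference in which Rpl29 passed. Chance is thus not excluded for the interaction, but these shares do not measure it.

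The response to fasting differed between genotypes past the camera threshold for 19 lists, and for 0 with an estimated correlation (smallest adjusted p 0.51). Some of these lists share members, such as Hal, Gls2, Arg1 and Ass1 in the periportal and amino acid lists, so they are not independent. The response was more positive in knockout livers for lipid droplets (1.2e-06), stellate cells (2.6e-05), fatty acid synthesis (4.2e-05) and fatty acid oxidation and ketogenesis (4.2e-05). It was also more positive for female-biased genes (0.0013), antioxidant defence (0.015) and glycolysis (0.019). It was more negative for male-biased genes (6.3e-08), amino acid breakdown and urea cycle (3.6e-06), cholesterol synthesis (2.1e-05), acute phase proteins (5.1e-05), periportal genes (0.00037), neutrophils (0.0004), gluconeogenesis (0.0042), heat shock (0.012), B and plasma cells (0.012), cholangiocytes (0.013), Kupffer cells (0.015) and T and NK cells (0.02). On the ranked edgeR statistic, T and NK cells missed the threshold with all libraries (0.16) and in 10 of the 12 fits without 1 library, cholangiocytes in 7 of these fits (up to 0.31), heat shock in 4 (0.14), Kupffer cells in 4 (0.55), glycolysis in 3 (0.087), and B and plasma cells, cholesterol synthesis and antioxidant defence in 1 each (0.27, 0.066 and 0.095). Among genes with too few counts to be tested, Speer6-ps1 had 10 counts over 3 of the 6 knockout libraries and 0 over the 6 control libraries (Fisher's exact test on libraries, 2-sided, p = 0.18); 2 genes had at least as many counts in knockout libraries alone and 11 in control libraries alone.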

How the results depend on the processing

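The alternatives with protein-coding genes only, without mitochondrial genes, without fed control replicate 3 plus block, with quality weights, with DESeq2 adjusted over the genes of the edgeR test and with camera on ranked edgeR statistics were added after seeing the data. A set of 49 named gene calls was followed through the alternatives, without the fasting calls of Tsc22d3 and Fst given below. Of these, 35 held in every fit without 1 library. In all other alternatives set beforehand 38 held, and 35 held in both kinds. The 2-fold minimum was not applied to single calls and is not part of these counts. Of these 49 calls, 0 changed direction. Of the called lists, 0 passed in the other direction, and a list that turned without passing was counted only as lost. The main counts (higher and lower genes) were 0 and 0 for knockout fed, 4 and 1 fasted, 2 and 0 mean, 325 and 332 for fasting in control, 215 and 178 in knockout, and 1 and 0 for the interaction, with 15, 8, 6, 9, 16 and 19 lists. The cause was not tested for the changes below, except that fewer genes or libraries enter where the setting says so.

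In the order knockout fed, fasted and mean, fasting in control, in knockout, and interaction, DESeq2 gave 15, 26, 27, 543, 398 and 37 higher and 20, 15, 19, 627, 393 and 23 lower genes, with 23, 13 and 12 lists for the 3 genotype comparisons and 17 for fasting in control. Adjusted over the genes of the edgeR test it gave 18, 26, 27, 541, 400 and 38 higher and 13, 15, 19, 630, 395 and 23 lower genes, with 10 lists for the mean. With no filter the fed knockout had 5 higher genes, the fasted one 8 higher and 5 lower, the mean 1 higher and 3 lower with 11 lists, and the interaction 4 lower. With limma-voom the fasted knockout had 2 higher and 0 lower genes (edgeR 1; 1375 at an unadjusted p under 0.05) and the mean 1 higher. On log2(TPM + 1) the fasted knockout had 0 lower genes (1098 at an unadjusted p under 0.05) and the mean 1 higher. On log2(TPM + 0.1) the fed knockout had 2 higher and 2 lower genes, the mean 2 lower and the interaction 3 higher. With only the groups compared, the fed knockout had 1 higher gene, the fasted one 1 higher and 0 lower (1204 at an unadjusted p under 0.05), and fasting in control 123 higher and 189 lower. With the replicate block, the fasted knockout had 0 lower genes (1177 at an unadjusted p under 0.05), fasting in control 221 lower, and fasting in knockout 117 higher and 115 lower. Correlations of the 18 same-number pairs across groups ran from -0.284 to 0.184, and 3 of 12 libraries correlated best with their own number. No strong pairing by replicate number was thus seen, but these values cannot exclude a shared litter or day. Without fed control replicate 3 and with that block, the fasted knockout had 8 higher genes and fasting in control 63 higher and 143 lower. Protein-coding genes only gave 2 higher genes in the fasted knockout. Quality weights gave 3 higher genes in the fed knockout, 0 lower in the fasted one, 331 higher and 317 lower with 10 lists for fasting in knockout. Upper-quartile factors gave 5 lists in the fasted knockout. A minimum of 2-fold left 90 higher and 141 lower genes for fasting in control and 72 and 93 in knockout. With an estimated correlation camera called 0 lists in each comparison, and fry 0, 0, 0, 4, 3 and 0.

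Leaving out each library in turn gave 0 to 0 higher and 0 to 1 lower genes for knockout fed, 1 to 5 and 0 to 3 fasted, 1 to 2 and 0 to 1 mean, 117 to 317 and 149 to 331 for fasting in control, 41 to 295 and 47 to 278 in knockout, and 1 to 3 and 0 to 1 for the interaction, with 15 to 23, 5 to 11, 5 to 14, 11 to 17, 12 to 19 and 16 to 26 lists. These list counts and those of the other gene tests come from camera on ranked statistics, which gave 15, 9, 6, 11, 15 and 19 lists with all libraries in edgeR. In simulated counts with the spread of these libraries, 36% to 78% of 2-fold changes and 86% to 97% of 4-fold changes were recovered over the 6 comparisons. In the fed, fasted and mean genotype comparisons it was 64%, 63% and 78% of 2-fold changes. Of 4-fold changes it was 86%, 90% and 97%. Only genes with a mean of at least 1 CPM were changed. In these 3 simulations 161, 165 and 195 genes were called, against 0, 5 and 2 in the real comparisons. The Benjamini-Hochberg cutoff is stricter when fewer genes are called. The recovered shares can therefore overstate what is found where few genes change. Many 2-fold and some 4-fold changes could thus be missed in the genotype comparisons, as could smaller ones.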

Other observations

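The list relations below were planned, and the single genes were chosen after their values were seen. Tsc22d3, a glucocorticoid-induced gene, rose in fasted controls by 1.94 (log2, SE 0.14, adjusted p = 2.3e-05) and in fasted knockouts by 0.72 (SE 0.13, adjusted p = 0.016); its interaction was -1.22 (SE 0.19, adjusted p = 0.14). Fst, encoding the activin inhibitor follistatin, changed by -1.10 in fasted controls (SE 0.26, adjusted p = 0.035) and by -2.38 in fasted knockouts (SE 0.26, adjusted p = 0.001), with an interaction of -1.28 (SE 0.37, adjusted p = 0.55).

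Single libraries held further outlying genes. Fasted knockout replicate 1 had 51 CPM of Rps3a1, a ribosomal protein gene at 226 CPM or more elsewhere. It also had 89 and 101 CPM of the near-identical copies Rps3a2 and Rps3a3, at 2.61 and 1.41 CPM or less elsewhere. Summed over Rps3a1 and its 6 near-identical copies, fasted knockout livers were at 264 ± 19 CPM. The sum was 266 ± 33 CPM in fed control, 283 ± 8.7 in fasted control and 299 ± 19 in fed knockout livers. Fasted control replicate 2 had 60.2 CPM of Eno1b, a copy of the enolase gene Eno1, against 8.22 CPM or less elsewhere. Fed control replicate 3 had 476 CPM of the glutathione transferase gene Gstm3 (69 CPM or less elsewhere), 35 CPM of Ly6d (6.29 or less) and 19 CPM of the macrophage gene Gpnmb (3.24 or less).

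A hypothesis was that the growth hormone dependent sex programme of the liver varies between these aged males, which would set male-biased and female-biased genes against each other between animals of the same group. Over the 12 libraries, the deviations of the list means from their group means had r = -0.69 (permutation p = 0.034, adjusted over 3 relations 0.1) and rho = -0.53 (permutation p = 0.17, adjusted 0.51). Without the 2 libraries farthest from the median of the male-biased list, fed control replicates 2 and 3, r was -0.56 (permutation p = 0.16), so the relation rests in part on those libraries and stays open. The other relations computed, of male-biased with acute phase genes (r = 0.23, permutation p = 0.34, adjusted 0.51; rho = 0.29, permutation p = 0.34) and of female-biased with interferon response genes (r = 0.19, permutation p = 0.69; rho = 0.11, permutation p = 0.78), did not pass. Without fed control replicates 2 and 3, male-biased and acute phase genes had r = 0.64 (permutation p = 0.097). Without fed control replicate 3 and fasted control replicate 2, female-biased and interferon response genes had r = -0.28 (permutation p = 0.53). No batch is named in the labels, so no value within batches can be given.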
